A study of Mus musculus with 2 samples.

How the data were processed

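Tissue sections were methanol-fixed, stained, imaged and hybridised with probe pairs, and the ligated products were transferred to Visium slides by a CytAssist instrument and sequenced on an Illumina NovaSeq, per the labels' protocols. The deposited values are UMI counts per gene and spot, made by Space Ranger 3.1.1 per the file headers. The submitters' processing notes name the mm10 build. The probe set version and the settings of the counting are not given in the sources used here. The matrix of each of the 2 samples was deposited with a list of spot positions, which also marks the spots over tissue. The deposited counts are whole numbers with no normalization. Pixel positions and image scale factors were not used here. Gene names are those of the deposited feature table, in which 11 symbols are shared by several gene IDs and were kept apart by ID.

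The files of the 2 samples were first compared. The matrix, barcode and feature files were the same byte for byte, and the position lists and scale factors were not. The library was therefore used once. The planned comparison of G2-3 with WT in each region, with its gene lists, was not made, and all results compare regions within 1 library. Spots were kept where the WT list marks tissue and where at least 500 UMIs were counted, which left out 2 spots. The WT list was chosen after its marked spots were seen to have counts throughout, and the choice does not assign a genotype, since the lists could themselves be exchanged. The grid places of the 2722 barcodes are the same in both lists.

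Spots were clustered with scanpy 1.11.5 (anndata 0.12.19, igraph 0.11.9, Python 3.11.15). Counts were scaled to 10000 per spot and log-transformed, and 2000 variable genes were taken among those seen in at least 10 spots. These gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1 with random seed 0. All genes of the function and cell type lists were left out of the variable genes, so that their own levels did not define the regions between which they are compared. Other genes that vary together with them were not left out. The cell content of spots could therefore still shape the regions, and the list comparisons are not independent of the clustering. No doublet caller was run, since a spot can hold several cells, and no deconvolution was run.

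Regions were named from 14 fixed lists of region markers. The markers were fixed before the data were examined, but the numeric rule was set after seeing the clusters. A cluster took a name if at least 3 markers of that class had a log2 fold of at least 1 over all other spots (CPM plus 10), more than of any other class, if its marker of highest fold belonged to the class, and if at least 1 of the class was among its 10 leading genes. The last condition was added after the Ddn/Gng7 region had first been called meninges. The Slc6a3/Th region stayed unnamed under this rule and was used for the ventral midbrain because its leading marker is nigral. A region led by Tph2 and Slc18a2 had more nigral markers past the threshold, but its leading marker was Tph2, of the midbrain and hindbrain list. The Ddn/Gng7 and Gpr161/Fezf2 regions were also singled out after seeing the clusters, by their place beside the dentate gyrus. A region led by Klk6 and Gfap was named white matter and one led by Mgp and Igf2 meninges. The naming rule was not stable when the spots were clustered again. At Leiden resolution 1.5 it named 89 spots cortex in place of 531. At this resolution it also named a cluster of 100 spots, led by Slc6a3 and Th, as substantia nigra and ventral midbrain. The values of that cluster alone were not computed. No cluster had a nigral marker as its marker of highest fold at resolution 0.6, without a UMI minimum, or with all barcodes. Each cluster of an alternative was therefore carried to the region that held most of each new cluster's spots, a change made after that was seen. At resolution 1.5 the nigral cluster was thus pooled with others into 503 spots, which kept 94.0% of the Slc6a3/Th region.

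For each comparison, counts were summed over the spots of a region and scaled by the region's total (CPM). The log2 ratio of 2 regions has an exact conditional interval for the ratio of 2 Poisson counts (Clopper-Pearson, 95%), computed with scipy 1.17.1 and numpy 2.4.6. A count of 0 was set to 3 counts over the region for the value. Genes with at least 100 counts over both regions were used. This minimum was applied again wherever an alternative changed the spots, so a list's median can then rest on different genes. A gene seen only in the region with fewer UMIs needs a higher CPM to pass it. With 1 section, spots are not replicates, so no p-value, standard error or test-based count is given, and the intervals and the 3-count floor cover counting error only. There is a difference of depth behind the values: the dentate gyrus sums to 1785170 UMIs, cortex to 5871162, the Slc6a3/Th region to 2353886, the Ddn/Gng7 region to 629519 and the Gpr161/Fezf2 region to 1892157.

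A total of 12 function lists and 12 cell type lists were fixed before the data were examined. The function lists were postsynaptic, inhibitory postsynaptic, presynaptic, synuclein family and chaperones, phagocytic microglia, complement, inflammatory, interferon response, reactive astrocyte, immediate early, mitochondrial respiration, and lysosome and autophagy. The cell type lists were homeostatic microglia, astrocyte, oligodendrocyte, oligodendrocyte precursor, endothelial, pericyte and smooth muscle, meningeal fibroblast, choroid plexus and ependyma, blood, glutamatergic, GABAergic and dopaminergic neuron. Some genes stand in several lists: 8 oligodendrocyte genes are also white matter markers and 10 dopaminergic genes are in another list. Of the phagocytic microglia genes, Spp1 is also a marker of the midbrain and hindbrain. A list is named for what its genes were chosen for. Which cells of a spot carried a transcript was not measured, so the phagocytic microglia list does not measure microglia alone. Of the list genes, Hspa8, Clec7a, Isg15, Ly6c1, Hba-a1, Ndufa4, Cox4i1 and Cox5a are not analysed here. A list's value is the median log2 ratio of its measured genes. Its percentile is taken among 10000 random lists of the same size, each member drawn from the 50 genes nearest in mean expression, and describes this library only. The interval of a median comes from drawing each count again from a Poisson distribution. Lists with fewer than 3 measured genes have no percentile.

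The genes named were set by a rule before the data were examined: for each comparison, the 4 highest and 4 lowest log2 ratios among genes not used for clustering, and the 2 members of each list with the largest absolute log2 ratio. Some of the genes that this rule gives are not reported here. Values of the Ddn/Gng7 and Gpr161/Fezf2 regions are given for 7 of the lists, a choice made after seeing the data. Region markers and the leading genes of regions are named to say what the regions are.

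The functions were tested on counts simulated from the dentate gyrus and cortex for 8395 genes. The interval held the true ratio for 97.1% of 103 genes set 2-fold apart and 93.8% of 97 genes set 4-fold apart, and excluded 0 for 4.12% of unchanged genes. Of 100 unchanged lists, 1 lay outside the central 95% of random lists. The simulated counts were Poisson draws, as the intervals assume, independent between genes, and the unchanged lists were genes drawn at random. Genes of the fixed lists may vary together, and many genes differ between the real regions. The simulation therefore checks the computation and does not show how often such lists reach an extreme percentile.

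The alternatives planned before the data were examined were TMM scaling (edgeR 4.0.16 in R 4.3.3), the mean of each spot's CPM, a minimum of 20 counts per gene, no UMI minimum or 2000 UMIs per spot, Leiden resolutions of 0.6 and 1.5, keeping the list genes for clustering, interior spots only and the lower and the higher columns of the array by themselves. With TMM the log2 ratios over all genes shifted by 0.14 for the dentate gyrus over the Slc6a3/Th region, by -0.11 for the Slc6a3/Th region over cortex and by at most 0.06 in size elsewhere. Added after seeing the data were another Leiden seed, all barcodes, the G2-3 tissue marks, the pooled hippocampus, a cortex with the Adam33/Penk and Tshz2/Nrep regions, a cortex without the Nxph3/Cplx3 region, and only spots with Th or Slc6a3.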

Results

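Brain sections of 6-month-old male mice were profiled with Visium CytAssist, a probe-based spatial assay. Pairs of probes are ligated on their transcripts in the tissue, moved to a slide of barcoded spots and counted as unique molecular identifiers (UMIs). The labels name 2 samples, 1 section of a G2-3 mouse, a line that carries alpha-synuclein with the A53T change, and 1 section of a wild-type (WT) mouse. The title of the series concerns hippocampal synapses and microglial phagocytosis, and the region comparisons below cover the genes of both.

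The count matrices deposited under the 2 samples were the same file. Of 8667725 nonzero entries, 0 differed, so the matrices, as copies of 1 file, differed by less than the sampling noise and were counted as 1 library. This says nothing on how far the 2 animals differ. No gene could be compared between G2-3 and WT, and no genotype is assigned to the library. The lists of spot positions did differ. The WT list marked 2487 spots as tissue, and all of them had counts. The G2-3 list marked 2969 spots as tissue, of which 751 had no counts. The library held 21695663 UMIs on 2722 spots, from 15891 genes with at least 1 UMI out of 19465 in the panel. The tissue spots used below, which were marked in the WT list and had at least 500 UMIs, numbered 2485. Their median depth was 6686 UMIs and 3219 genes per spot, with a range of 1183 to 80174 UMIs. All values come from 1 section of 1 animal, so nothing below has a replicate check, and every interval covers counting error only.

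Clustering divided the section into 15 regions, which are called here by their leading genes. The region led by C1ql2 and Pcdh20 carried 9 of the fixed hippocampal markers, among them the granule cell genes Prox1 and Dsp. It is called the dentate gyrus, as a name for these spots only. It covered 55 spots, with a median of 30411 UMIs. The 3 bands that met the rule for cortex were pooled, giving 531 spots with a median of 10451 UMIs. These were led by Clec18a and Igfn1 (178 spots), by Vxn and Myl4 (266 spots) and by Nxph3 and Cplx3 (87 spots). A region led by Slc6a3 and Th, the dopamine transporter and the rate-limiting enzyme of dopamine synthesis, covered 502 spots with a median of 4602 UMIs. This Slc6a3/Th region stood in for the ventral midbrain, but it was far wider than the substantia nigra. Only 62 of its spots (12.4%) had a UMI of Th and 68 had a UMI of Slc6a3, and 8 white matter markers passed the marker threshold in it, against 5 nigral ones. The same 5 and also Ddc passed in a region of 94 spots led by Tph2 and Slc18a2. The Slc6a3/Th region held 246 of the 299 Slc6a3 UMIs and 185 of the 260 Th UMIs. It held only 133 of 496 for Slc18a2 and 26 of 110 for Ddc. Against all other spots, the dopaminergic median log2 ratio was 2.61 in the Tph2/Slc18a2 region and 1.60 in the Slc6a3/Th region.

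The dentate gyrus was surrounded on most sides by a region led by Ddn and Gng7, in 168 spots with a median of 3386.5 UMIs. Ddn encodes dendrin, a dendritic protein. An arc led by Gpr161 and Fezf2, in 166 spots with a median of 11101 UMIs, lay between this region and the deep cortical bands. Neither met the rule for a named region. Among the markers that passed the threshold in the Ddn/Gng7 region were 3 of meninges (Col1a1, Igf2 and Slc6a13) and 2 of the dentate gyrus (Dsp and Prox1). The Gpr161/Fezf2 arc had 4 hippocampal markers (Cpne7, Mpped1, Nnat and Pex5l), more than of any other class, but its marker of highest fold was Fezf2, from the deep cortical list. A hippocampus outlined by anatomy would be wider than the region called the dentate gyrus. Since Dsp and Prox1 also passed in the Ddn/Gng7 region, parts of the dentate gyrus itself may lie outside the C1ql2/Pcdh20 region. Values for the dentate gyrus pooled with both regions are therefore also given for results that they turn.

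**Figure D1:**
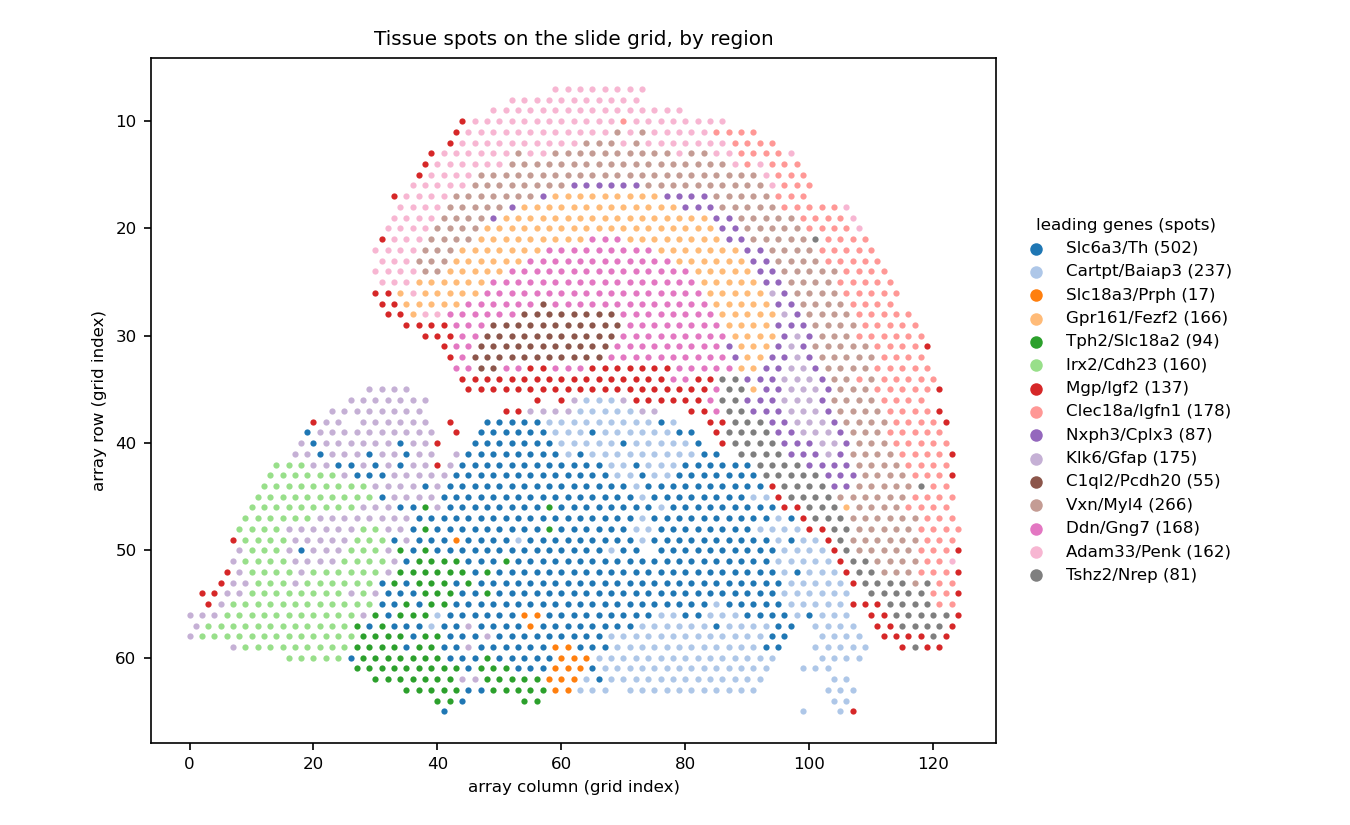
Position of the 2485 tissue spots on the slide grid (horizontal axis, array column; vertical axis, array row, both as grid indices), coloured by the region each was clustered into, with the number of spots of each region in the key. The 55 spots of the C1ql2/Pcdh20 region (dentate gyrus) are surrounded on most sides by the 168 spots of the Ddn/Gng7 region, which the 166 spots of the Gpr161/Fezf2 region border on the cortical side.

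The comparison of the dentate gyrus with cortex asked how synaptic and glial transcripts differ between them within this section. Postsynaptic genes were close to cortex as a group, while genes of inhibitory postsynapses were higher and presynaptic genes lower. The median log2 ratio of the 30 measured postsynaptic genes was 0.13 (0.02 to 0.20, percentile 81.7 among matched random lists), with 16 higher and 14 lower. Lrrtm1, a postsynaptic adhesion protein, was 4.53-fold higher (log2 ratio 2.18, 1.94 to 2.43), and Gria1, an AMPA receptor subunit, was 3.61-fold higher (1.85, 1.76 to 1.95). Of 12 inhibitory postsynaptic genes 10 were higher (median 0.50, 0.36 to 0.59, percentile 99.4), among them the GABA-A receptor subunit Gabra4 (0.70, 0.49 to 0.91). This median fell as low as 0.15 under the alternatives. Of 24 presynaptic genes 21 were lower (median -0.48, -0.61 to -0.39, percentile 0.08). The synaptic vesicle gene Sv2b had 2 UMIs in the dentate gyrus and 943 in cortex (log2 ratio -7.16, -10.21 to -5.31). The inhibitory vesicle transporter Slc32a1 had 3 against 119 (-3.59, -5.89 to -2.01).

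Glial transcripts took a smaller share of the UMIs in the dentate gyrus than in cortex. The median log2 ratio was -0.64 for 13 phagocytic microglia genes (-0.82 to -0.47, percentile 1.2, 11 lower) and -0.71 for the 4 homeostatic microglia genes with enough counts (-1.11 to -0.39, percentile 13.5). It was -1.02 for 5 complement genes (-1.18 to -0.76, percentile 0.98, 4 lower), but -0.28 in the higher columns of the array, which hold 468 of the cortex spots and 13 of the dentate gyrus. Among the phagocytic microglia genes, the lysosomal protease gene Ctsz was 3.37-fold lower (-1.75, -2.42 to -1.15), and Trem2, a microglial receptor for lipids, 3.02-fold lower (-1.59, -2.47 to -0.83). Selplg (-1.09, -1.57 to -0.64) and the fractalkine receptor gene Cx3cr1 (-0.91, -1.71 to -0.18) were the homeostatic genes of largest difference. C1qb (-1.31, -2.04 to -0.65) and C1qa (-1.03, -1.31 to -0.76) encode subunits of the complement initiator C1q. Of 19 inflammatory genes only Nfkbia (-0.49, -1.31 to 0.26) and Il18 (-0.18, -0.88 to 0.47) reached 100 counts, and neither differed beyond counting error. Of 13 astrocyte genes 12 were lower (median -1.06, -1.18 to -0.98, percentile 0.02, and -1.75 to 0.27 over the alternatives), with Aldh1l1 at -2.31 (-2.87 to -1.80) and Fgfr3 at -1.53 (-1.90 to -1.18). The reactive astrocyte genes went the other way (3 of 3 higher, median 0.72, 0.46 to 0.96, percentile 92.4, and 0.11 to 2.07 over the alternatives): the protease inhibitor gene Serpina3n was 9.21-fold higher (3.20, 2.59 to 3.86) and Gfap 1.64-fold (0.72, 0.45 to 0.98). All 11 oligodendrocyte genes were at least 2-fold lower (median -3.71, -4.01 to -3.21, percentile 0). Opalin had 1 UMI against 135 (-5.36, -10.67 to -2.86) and the tight junction gene Cldn11 had 4 against 279 (-4.41, -6.29 to -3.03).

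The direction of some of these glial ratios changed with the outline of the hippocampus. With the Ddn/Gng7 and Gpr161/Fezf2 regions pooled into the hippocampus, medians over cortex that were negative became 0.14 for phagocytic microglia, 0.25 for homeostatic microglia, 0.34 for complement and 0.27 for astrocytes. Those of blood (1.16), endothelial (0.081), interferon response (0.22), dopaminergic neuron (1.16), lysosome and autophagy (0.056) and mitochondrial respiration genes (0.19) changed sign too. So did the single genes C1qa (0.081), C1qb (0.27), Cx3cr1 (0.19), Fgfr3 (0.21), Uqcrfs1 (0.21) and Vtn (0.83). The pooled postsynaptic median was 0.11, the presynaptic -0.34, the oligodendrocyte -0.63, the oligodendrocyte precursor -0.047, the reactive astrocyte 2.07, the GABAergic -0.80 and the immediate early -1.30. Spots of the dentate gyrus held 2.94 times as many UMIs on average as those of cortex.

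Interneuron and activity genes were also lower in the dentate gyrus than in cortex. All 11 GABAergic neuron genes were lower (median -2.38, -2.99 to -2.02, percentile 0, and -4.77 to -0.80 over the alternatives), with the neuropeptide genes Sst at 49 against 9193 UMIs (-5.83, -6.27 to -5.43) and Vip at 6 against 626 (-4.99, -6.44 to -3.86). Of 8 immediate early genes 7 were lower (median -2.92, -3.63 to -2.51, percentile 0). Fos had 2 UMIs against 272 (-5.37, -8.42 to -3.50) and Nr4a1 had 10 against 909 (-4.79, -5.85 to -3.90). The mitochondrial respiration median was -0.14 (-0.18 to -0.03, percentile 18.5), with Uqcrfs1 at -0.28 (-0.54 to -0.03). Medians were -0.21 for lysosome and autophagy genes (percentile 18.2), -0.06 for the synuclein family and chaperones (41.2) and -0.91 for interferon response genes (6.4). They were -2.26 for oligodendrocyte precursor genes (1.58), -1.71 for endothelial genes (6.24) and -0.56 for blood genes (35.7). Glutamatergic neuron genes were at -0.19 (27.0) and 3 measured dopaminergic neuron genes at -1.01 (3.4). Of these lists, all but the oligodendrocyte precursor list lay within the central 95% of matched random lists. The pericyte, meningeal fibroblast and choroid plexus lists had a single measured gene each, Vtn (-1.15), Igf2 (1.16) and Enpp2 (-3.15). Of the 8395 genes with at least 100 counts, 541 were at least 2-fold higher in the dentate gyrus and 1109 at least 2-fold lower. Leaving out the genes that were used to find the regions, 436 of 7568 were higher and 782 lower. Cortex had 5871162 UMIs against 1785170 in the dentate gyrus. Genes seen only in cortex therefore passed the count minimum at a lower CPM than genes seen only in the dentate gyrus. The filter thus favours genes that are lower there, and the split depends on it. The total of 1650 genes became 2835 with a minimum of 20 counts and 615 with the pooled hippocampus. The highest and lowest genes given here and below are among those not used to find the regions. The highest were Tspan18 (86.2-fold), the keratin gene Krt2 (80.9-fold), the neuropeptide Y receptor gene Npy2r (39.0-fold) and the ATP receptor gene P2rx5 (32.3-fold). Among the lowest were Hs3st2 (1 UMI against 523; log2 ratio -7.31, -12.62 to -4.83), Sv2b and the cholecystokinin receptor gene Cckbr (2 against 743; -6.82, -9.87 to -4.96).

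Against the Slc6a3/Th region, excitatory postsynaptic transcripts took a larger share of the UMIs in the dentate gyrus and glial ones a smaller share. Of 29 postsynaptic genes 27 were higher (median log2 ratio 1.86, 1.65 to 1.99, percentile 100), with the spine scaffold gene Baiap2 8.95-fold higher (3.16, 2.99 to 3.34) and Lrrtm1 7.68-fold (2.94, 2.53 to 3.37). Of 12 inhibitory postsynaptic genes 8 were higher (median 0.97, 0.77 to 1.12), led by the GABA-A receptor subunits Gabrd (3.80, 2.81 to 4.97) and Gabra4 (6.37-fold). Presynaptic genes were split, with 10 higher and 14 lower (median -0.21, -0.36 to -0.09). Slc17a6, the vesicular glutamate transporter of subcortical neurons, had 0 UMIs in the dentate gyrus and 163 in the Slc6a3/Th region, at least 41.2-fold lower when the 0 is set to 3 counts over the region. Slc32a1 had 3 against 117 (-4.89, -7.18 to -3.30). The presynaptic median turned to 0.12 with the pooled hippocampus, and to 0.091 with only the 88 spots of the Slc6a3/Th region that had a UMI of Th or Slc6a3.

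All 10 phagocytic microglia genes measured in this comparison were lower in the dentate gyrus (median -1.52, -1.69 to -1.29, percentile 0.06), as were all 5 complement genes (-1.58, -1.83 to -1.31, percentile 0.24). The engulfment receptor gene Megf10 was the lowest of them (-3.33, -4.58 to -2.30), followed by Trem2 (-2.17, -3.07 to -1.37), and among the complement genes C1qb was 4.73-fold lower (-2.24, -2.98 to -1.57) and C1qa 3.03-fold (-1.60, -1.89 to -1.32). Only 2 homeostatic microglia genes had enough counts, among them Selplg (-1.29, -1.81 to -0.80), and no inflammatory gene did. Of 13 astrocyte genes 12 were lower (median -1.87, -2.15 to -1.67, percentile 0, and -2.71 to -0.51 over the alternatives), with S100b at -3.39 (-3.64 to -3.15) and the water channel gene Aqp4 at -2.66 (-3.41 to -1.99). The phagocytic microglia list thus went the same way as the astrocyte list, and which cells carried its transcripts was not measured. Of 3 reactive astrocyte genes, Gfap (interval -1.26 to -0.74) and Vim (-0.94, -1.41 to -0.49) were lower, but both were higher, at 0.35 and 0.46, with the pooled hippocampus. All 13 oligodendrocyte genes were lower (median -5.67, -6.20 to -5.39). With the pooled hippocampus the medians were smaller, at -0.54 for phagocytic microglia, -0.67 for complement and -0.51 for astrocytes. Dentate gyrus spots held 6.92 times as many UMIs on average as those of the Slc6a3/Th region, and counted per spot the medians were 1.27 for phagocytic microglia, 1.52 for homeostatic microglia, 1.21 for complement, 0.93 for astrocytes and -2.88 for oligodendrocytes. The myelin genes Opalin (1 UMI against 176; -7.06, -12.37 to -4.56), Mog (-6.87, -8.76 to -5.51) and Mobp (-6.85, -7.22 to -6.50) were among the lowest 4 genes, with Plcxd2 (1 against 144; -6.77, -12.08 to -4.27). The highest 4 were the epithelial sodium channel gene Scnn1a (2 UMIs in the Slc6a3/Th region; 6.47, 4.58 to 9.53), Krt2 (6.34, 4.46 to 9.40), Ntn5 (55.1-fold) and the neurotrophin gene Ntf3 (54.5-fold). Of 6889 genes, 884 were at least 2-fold higher and 1177 lower (764 and 719 of the 6125 not used to find the regions), and the total of 2061 became 3805 with a minimum of 20 counts. With TMM scaling 1043 were higher and 1021 lower, so which side held more genes depends on the scaling.

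The Slc6a3/Th region and cortex were compared in the same way. All 30 postsynaptic genes were lower in the Slc6a3/Th region (median -1.15, -1.32 to -1.08, percentile 0), 18 of them at least 2-fold. Nrgn, a calmodulin-binding protein of dendritic spines, was 15.9-fold lower (-3.99, -4.23 to -3.76) and the scaffold gene Dlgap2 8.62-fold (-3.11, -3.57 to -2.68). Gabrd (-3.40, -4.55 to -2.45) and Gabra4 (-1.97, -2.38 to -1.58) were lower among the inhibitory postsynaptic genes (median -0.41, -0.55 to -0.25), of which 7 were lower and 5 higher. Of 25 presynaptic genes 18 were lower (median -0.41, -0.59 to -0.37), and the vesicular glutamate transporters went opposite ways, with Slc17a7 18.0-fold lower (-4.17, -4.28 to -4.05) and Slc17a6 10.4-fold higher (3.38, 2.87 to 3.93). All 8 immediate early genes were lower (median -2.27, -2.50 to -1.97), with Egr1 at -2.96 (-3.39 to -2.57) and Fosb at -2.84 (-4.32 to -1.67).

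Glial groups took a larger share of the UMIs in the Slc6a3/Th region than in cortex. The median was 0.58 for phagocytic microglia (0.55 to 0.88, percentile 99.8, 13 of 15 higher), 0.65 for homeostatic microglia (0.39 to 0.86, percentile 98.0, 6 of 6) and 0.75 for complement (0.61 to 0.98, percentile 99.0, 6 of 6). Megf10 (1.72, 1.29 to 2.16), Cd63 (1.47, 0.96 to 1.97), the purinergic receptor gene P2ry12 (0.93, 0.41 to 1.44) and C4b (1.86, 1.56 to 2.16) were among those that differed most. Of the inflammatory genes, Nfkbia was 2.22-fold higher (1.15, 0.68 to 1.62) and Il18 did not differ beyond counting error (0.39, -0.14 to 0.91). Medians were 0.81 for astrocyte genes (Aqp4 1.97, S100b 1.89), 1.35 for reactive astrocyte genes (Gfap 1.72, Tgm2 1.35) and 2.67 for the 13 oligodendrocyte genes (2.57 to 2.71, percentile 100, and 2.15 to 3.68 over the alternatives), with Ermn at 3.66 and Ugt8a at 3.00. Interferon response (1.06), oligodendrocyte precursor (1.27), endothelial (0.89), blood (1.52, and 0.97 to 2.55 over the alternatives), lysosome and autophagy (0.47) and mitochondrial respiration genes (0.44, 12 of 12 higher) were all on the same side. Spots of this region held 0.424 times as many UMIs on average as those of cortex. Counted per spot, medians were therefore -0.65 for phagocytic microglia, -0.58 for homeostatic microglia, -0.49 for complement and -0.42 for astrocytes, while that of oligodendrocytes was 1.43. The choroid plexus gene Ttr was 114-fold higher. Sncg, of the synuclein family, was 35.4-fold higher. Slc6a3, En1 and Slc18a2 were, with Ttr, the highest 4 genes, at 246, 162 and 133 UMIs against 1 each, but they are among the markers by which the region was recognised. The dopaminergic list (median 5.15) is no finding for the same reason. Among the lowest were Krt12 (1 UMI against 149; -5.90, -11.21 to -3.40), Tac2 (1 against 131; -5.71, -11.03 to -3.21) and Robo3 (2 against 258; -5.69, -8.75 to -3.83). Of 8773 genes, 723 were at least 2-fold higher and 697 lower (334 and 577 of the 7803 not used to find the regions), and the total of 1420 became 2433 with a minimum of 20 counts. TMM scaling gave 585 higher and 821 lower, so the even split also depends on the scaling. Here too the count minimum let in genes seen only in cortex at a lower CPM. In the higher columns of the array the homeostatic microglia median was -0.13, the complement median 0.16, the dopaminergic median 0.65 and the inhibitory postsynaptic median 0.012. In the lower columns the inhibitory postsynaptic median was -1.37.

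Around the dentate gyrus, the Ddn/Gng7 region differed from cortex in the direction opposite to the dentate gyrus for the microglial, complement, astrocyte and oligodendrocyte lists. Medians over cortex were 1.85 for phagocytic microglia (1.57 to 2.03, 12 of 14 higher) and 1.85 for homeostatic microglia (1.58 to 2.14, 5 of 5). They were 2.05 for complement (1.77 to 2.15, 5 of 5), 1.80 for astrocytes (1.74 to 1.96, 13 of 13) and 1.03 for oligodendrocytes (0.95 to 1.15, 11 of 11). Apoe was 6.05-fold higher (2.60, 2.52 to 2.67), Cd63 5.74-fold, P2ry12 5.64-fold, C4b 9.27-fold (3.21, 2.89 to 3.54) and Aqp4 12.5-fold (3.64, 3.27 to 4.02). Vessel and meningeal genes were higher in the same spots. The smooth muscle genes Acta2 (35.1-fold) and Myl9 (12.8-fold) and the meningeal fibroblast gene Igf2 (17.7-fold) were, with Gfap (18.8-fold), the highest 4 genes. The presynaptic median was -1.13 (-1.37 to -0.98, 23 of 24 lower), with Sv2b at -2.85 and Stx1a at -2.55. The postsynaptic median was -0.30 (-0.63 to -0.24, percentile 23.5), with Nrgn at -2.18 and Grin1 at -1.79. In the lower columns of the array the phagocytic microglia median was 0.25. Spots of this region held 0.339 times as many UMIs on average as those of cortex, and the median over all 8005 genes was itself -0.17. Over the dentate gyrus, the Ddn/Gng7 region had medians of 1.73 for phagocytic microglia (1.09 to 2.80 over the alternatives), 2.85 for complement (2.23 to 2.99), 3.15 for astrocytes (2.496 to 4.09), 4.15 for oligodendrocytes (3.62 to 5.25), -1.11 for postsynaptic genes (-1.35 to -0.74) and -0.37 for presynaptic genes (-0.72 to -0.25), against -0.33 over all genes.

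The Gpr161/Fezf2 arc was close to cortex. Medians were -0.09 for postsynaptic (-0.16 to -0.02), -0.03 for presynaptic (-0.17 to 0.03), 0.02 for phagocytic microglia (-0.16 to 0.20), -0.07 for homeostatic microglia (-0.55 to 0.20), -0.23 for complement (-0.42 to 0.07) and 0.19 for astrocyte genes (0.10 to 0.27). Oligodendrocyte genes were lower (-0.61, -0.70 to -0.50, 11 of 11). The oligodendrocyte median turned sign under 4 of the alternative settings, reaching 1.15 with the list genes kept for clustering. Other medians of the arc also crossed 0 under alternatives, reaching 0.38 for complement, 0.17 for homeostatic microglia, -0.22 for phagocytic microglia, 0.053 for presynaptic and 0.0079 for postsynaptic genes.

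**Figure D2:**
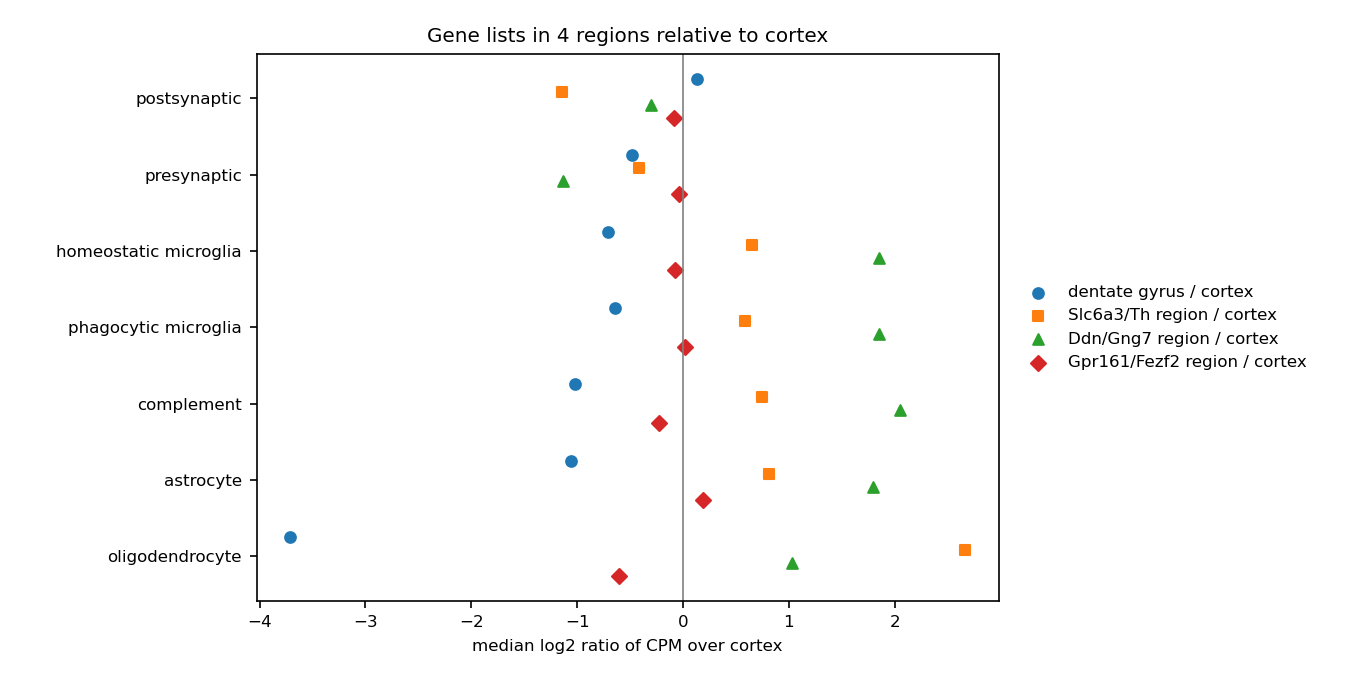
Median log2 ratio of CPM over cortex (horizontal axis) for 7 gene lists (vertical axis) in the dentate gyrus, the Slc6a3/Th region, the Ddn/Gng7 region and the Gpr161/Fezf2 region, with 1 point per list and region. Phagocytic microglia genes are at -0.64, 0.58, 1.85 and 0.02 in that order, and postsynaptic genes at 0.13, -1.15, -0.30 and -0.09.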

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

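The tests on matching matrices and on UMIs per spot were chosen only after the result was seen. The tests on white matter at the cortical edge and on spots beside the meninges were written before their own values were seen. Neither was part of the plan made before the data were examined, and the Ddn/Gng7 region was singled out after seeing the clusters. Spots that the WT list does not mark as tissue, which the comparisons left out except under 2 alternative choices of spots (all barcodes and the marks of the G2-3 list), carried more UMIs than the limit that a count of 0 allows (3 counts), which any sum of this size passes and which does not tell tissue from background. The 174 of them that touch a tissue spot held 657342 UMIs, with a median of 3392 per spot. The 61 that touch none held 40093 UMIs, with a median of 239. Across genes, their summed profiles correlated most with the Mgp/Igf2 meningeal region (Spearman's rho 0.90 over 8654 genes and 0.69 over 893 genes, and genes are not independent replicates).

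The matrices deposited for G2-3 and WT had 0 differing entries, which is consistent with 1 library under both sample names. In the G2-3 list 751 tissue spots had no counts, which argues against the section outlined there as the source, and in the WT list 0 tissue spots lacked counts. The matrix also held 235 barcodes that the WT list does not mark as tissue and 504 that the G2-3 list does not mark. It thus matched neither list exactly. Whether the 2 lists were themselves exchanged was not tested, so the genotype of the library stays open. No biological explanation was tested, since no second library was there to compare.

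Microglial, astrocyte and oligodendrocyte lists were lower in the dentate gyrus than in cortex as a share of UMIs. Per spot rather than per UMI, which multiplies the ratio of every gene by the same 2.94, genes of the microglial lists were higher (median log2 ratio 0.92, 0.67 to 1.05, and 0.53 and 0.92 in the lower and higher columns of the array), as were astrocyte genes (0.50, 0.36 to 0.58, and 0.14 and 0.60). Since 1 factor for all genes sets this change of sign, it is no separate support for RNA content as the cause, and greater RNA content and a true difference in these cells cannot be told apart. Oligodendrocyte genes were lower by more than that factor, and so stayed lower per spot (-2.16, -2.42 to -1.61, 11 genes). In the lower and higher columns, where the count minimum may leave other genes, they were less so, at -1.30 and -1.64. They were also lower by CPM against the Clec18a/Igfn1 upper cortical region alone (-2.11, -2.32 to -1.72, 7 genes). These values argue against RNA content and against white matter at the cortical edge, each by itself, as the whole cause. Both together were not tested, since the value against the upper cortical region was by CPM and leaves RNA content in. A true difference in oligodendrocytes between these places stays open, and no biological explanation was tested.

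Microglial lists were higher in the Ddn/Gng7 region than in cortex. In the 141 of 168 spots that touch no meningeal spot the median was still 1.88 (1.64 to 2.003), which argues against direct contact with the meninges as the cause, although these spots kept higher medians of meningeal fibroblast (3.16), blood (2.49), pericyte (2.31) and endothelial genes (1.70). At Leiden resolution 0.6 all 168 spots fell in a cluster of 310 spots that the rule named meninges. At that setting this cluster stood for the Ddn/Gng7 region in the ranges over the alternatives. Per spot, which multiplies every ratio by the same 0.339, the median was 0.29 (0.08 to 0.44) over the section but -1.55 and 0.09 in the lower and higher columns of the array. This rescaling is not specific to microglia. The parts of the array differ in sign, but the minimum of 100 counts was applied within each part, so their medians may rest on different genes. Lower RNA content and more microglial RNA per spot therefore cannot be told apart. No biological explanation was tested.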

How the results depend on the processing

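Tests with another seed, all barcodes, the marks of the G2-3 list, other outlines of hippocampus and cortex, and spots with Th or Slc6a3 were chosen only after the result was seen, as was the choice of the results counted as main. No paired analysis was possible because both samples hold the same matrix, and the alternatives foreseen for the G2-3 against WT comparison (TMM scaling, the mean of each spot's CPM, other minimums and clusterings, interior spots and parts of the array) were not run for the same reason. Over all alternatives, 2367 of 2387 values of named genes and 1155 of 1204 list medians kept their sign, and 44 of 50 counts of genes at least 2-fold different stayed within 1.5 times the first value. Over every gene the naming rule gives and every list, including those not reported, 55 of 4857 gene values and 100 of 1872 medians changed sign, and 511 gene values fell below the count minimum and were not computed. These gene totals do not measure how stable genes in general are. The named genes were picked by the size of their ratios, which makes a change of sign unlikely. The lower count minimum cannot change a gene's ratio, and all 161 named values stayed the same there. TMM scaling shifts every gene of a comparison by the same amount, at most 0.14 in size. With at least 2000 UMIs per spot, Leiden resolution 1.5 or either other outline of cortex, no reported value whose counting interval excludes 0 changed sign and no median of the postsynaptic, presynaptic, microglial or complement lists left its counting interval in the 3 main comparisons. The postsynaptic median of the dentate gyrus over cortex ranged from 0.03 to 0.22, and that of the Slc6a3/Th region over cortex from -1.42 to -1.11. The dentate gyrus kept 76.4% of its spots and the Slc6a3/Th region 73.1% with another seed. Depth limits several lists, with only 4 of 14 homeostatic microglia and 2 of 19 inflammatory genes at 100 counts in the dentate gyrus and cortex.

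Some of the values whose counting interval holds 0 changed sign. For the Gpr161/Fezf2 region over cortex these reached -0.22 for phagocytic (6 settings), 0.38 for complement (3), 0.17 for homeostatic (2) and 0.053 for presynaptic (2). The synuclein family and chaperone median reached 0.12 for the Slc6a3/Th region over cortex (9) and 0.064 for the dentate gyrus over the Slc6a3/Th region (TMM scaling). For the dentate gyrus over cortex, Il18 reached 0.33 (2) and Nfkbia 0.36 (pooled hippocampus).

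Medians of the postsynaptic, presynaptic, microglial and complement lists that left their counting interval in the 3 main comparisons, counts that moved beyond 1.5 times and values with an interval excluding 0 that changed sign follow by setting, and apart from the count minimum the cause was not tested. With TMM scaling, the dentate gyrus over the Slc6a3/Th region moved to 2.002 for postsynaptic and -0.069 for presynaptic. At the same setting, the Slc6a3/Th region over cortex moved to 0.48 for phagocytic. With the mean of each spot's CPM, the dentate gyrus over cortex moved to -0.57 for complement, -0.30 for homeostatic and 0.22 for postsynaptic. There, the dentate gyrus over the Slc6a3/Th region moved to -1.15 for complement, -1.24 for phagocytic and -0.061 for presynaptic. With a minimum of 20 counts, which lets in more genes, the dentate gyrus over cortex moved to 2835 for the count of genes at least 2-fold different. In this case, the dentate gyrus over the Slc6a3/Th region moved to 3805 for the count of genes at least 2-fold different and -0.37 for presynaptic, and changed sign to -1.95 for immediate early. Likewise, the Slc6a3/Th region over cortex moved to 2433 for the count of genes at least 2-fold different. Without a UMI minimum, the dentate gyrus over the Slc6a3/Th region moved to -1.20 for complement. Under the same choice, the Slc6a3/Th region over cortex moved to 0.37 for homeostatic. At Leiden resolution 0.6, the dentate gyrus over the Slc6a3/Th region changed sign to -1.05 for immediate early. At the same setting, the Slc6a3/Th region over cortex moved to 0.58 for complement and 0.29 for homeostatic, while the Gpr161/Fezf2 region over cortex changed sign to 0.93 for oligodendrocyte. With the list genes kept for clustering, the Slc6a3/Th region over cortex moved to 0.39 for homeostatic. There, the Gpr161/Fezf2 region over cortex changed sign to 1.15 for oligodendrocyte. In interior spots, the dentate gyrus over cortex moved to -1.47 for complement and -1.02 for phagocytic, and changed sign to 0.13 for lysosome autophagy. In this case, the dentate gyrus over the Slc6a3/Th region moved to -1.99 for complement and -1.14 for phagocytic, while the Slc6a3/Th region over cortex moved to -1.36 for postsynaptic. In the lower columns of the array, the dentate gyrus over cortex moved to 910 for the count of genes at least 2-fold different, 0.21 for postsynaptic and -0.33 for presynaptic. Likewise, the dentate gyrus over the Slc6a3/Th region moved to -2.19 for complement, while the Slc6a3/Th region over cortex moved to 1.014 for complement, -1.42 for postsynaptic and -0.71 for presynaptic. Under the same choice, the Gpr161/Fezf2 region over cortex changed sign to 0.091 for oligodendrocyte and 0.0079 for postsynaptic. In the higher columns of the array, the dentate gyrus over cortex moved to -0.28 for complement, and changed sign to 0.070 for Hbb-bs and 0.034 for mitochondrial respiration. At the same setting, the dentate gyrus over the Slc6a3/Th region moved to 1103 for the count of genes at least 2-fold different, -1.04 for phagocytic and 2.18 for postsynaptic, and changed sign to 0.19 for Gfap. There, the Slc6a3/Th region over cortex moved to 0.16 for complement, and changed sign to -0.13 for homeostatic and 0.012 for inhibitory postsynaptic. With another Leiden seed, the dentate gyrus over cortex moved to -1.26 for complement and -1.25 for homeostatic. In this case, the dentate gyrus over the Slc6a3/Th region moved to -2.19 for complement. With all barcodes, the dentate gyrus over cortex moved to -1.31 for complement and -1.31 for homeostatic. Likewise, the dentate gyrus over the Slc6a3/Th region moved to -2.06 for complement, -1.69 for phagocytic and -0.44 for presynaptic, and changed sign to -1.86 for immediate early, while the Slc6a3/Th region over cortex moved to 0.28 for homeostatic. With the tissue marks of the G2-3 list, the dentate gyrus over cortex moved to -1.19 for complement, -0.83 for phagocytic and -0.37 for presynaptic, and changed sign to 0.14 for Hbb-bs. At the same setting, the dentate gyrus over the Slc6a3/Th region moved to -1.84 for complement and -1.91 for phagocytic, while the Gpr161/Fezf2 region over cortex changed sign to 0.029 for oligodendrocyte. With the pooled hippocampus, the hippocampus over cortex moved to 615 for the count of genes at least 2-fold different and -0.34 for presynaptic, and changed sign to 0.081 for C1qa, 0.27 for C1qb, 0.32 for Cldn5, 0.19 for Cx3cr1, 0.21 for Fgfr3, 1.16 for Hbb-bs, 1.21 for Hbb-bt, 0.21 for Uqcrfs1, 0.83 for Vtn, 0.27 for astrocyte, 1.16 for blood, 0.34 for complement, 1.16 for dopaminergic, 0.081 for endothelial, 0.25 for homeostatic, 0.22 for interferon response, 0.056 for lysosome autophagy, 0.19 for mitochondrial respiration and 0.14 for phagocytic. There, the hippocampus over the Slc6a3/Th region moved to -0.67 for complement, -0.54 for phagocytic and 1.63 for postsynaptic, and changed sign to 0.73 for Arc, 0.35 for Gfap, 0.52 for Igf2, 0.46 for Vim, 0.49 for GABAergic, 0.12 for presynaptic and 0.35 for reactive astrocyte. In Slc6a3/Th spots with either gene, the dentate gyrus over the Slc6a3/Th region moved to -1.23 for phagocytic and changed sign to 0.091 for presynaptic. In this case, the Slc6a3/Th region over cortex moved to 1.012 for complement, 1.23 for homeostatic and -1.38 for postsynaptic, and changed sign to -0.38 for Flt1.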

Other observations

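Neuronal lists differed between the Slc6a3/Th region and the other regions. Over the Slc6a3/Th region, the dentate gyrus had a glutamatergic neuron median log2 ratio of 2.81 (2.70 to 2.98, 4 of 5 genes higher), with the neuronal transcription factor gene Neurod2 at 1320 against 56 UMIs (4.96, 4.57 to 5.37). Its GABAergic neuron median was -3.74 (-3.92 to -3.31, 5 of 7 lower), with Gad2, which encodes a GABA-synthesizing enzyme, at 21 against 465 UMIs (-4.07, -4.78 to -3.44). With the pooled hippocampus, an outline chosen after seeing the data, the GABAergic median was 0.49. Oligodendrocyte precursor genes were lower in the dentate gyrus (median -4.81, 3 of 3), as were endothelial (-2.44, 3 of 3) and interferon response genes (-1.88, 3 of 3), with -1.22, -0.71 and -0.63 in that order for the pooled hippocampus. The same held for lysosome and autophagy genes (-0.63, 11 of 15 lower) and mitochondrial respiration genes (-0.59, 12 of 12 lower), with Npc2, of cholesterol transport out of lysosomes, at -2.36 and Ndufb8, of respiratory complex I, at -1.08. The immediate early median of 1.57 rested on 3 genes and was -1.95 with a minimum of 20 counts, -1.05 at Leiden resolution 0.6 and -1.86 with all barcodes.

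The Slc6a3/Th region had lower glutamatergic (median -4.14, 7 of 8 genes lower) and GABAergic neuron genes (-2.08, 7 of 11 lower, but -0.96 in the lower columns of the array) than cortex, with the neuropeptide genes Npy at 30 against 2045 UMIs (-4.77, -5.34 to -4.25) and Vip at 13 against 626 (-4.27, -5.19 to -3.49). The other 4 GABAergic genes were each at least 2-fold higher, as was Slc17a6 of the glutamatergic list, so neither list was lower throughout. The synuclein family and chaperone list had a median of -0.01 (-0.08 to 0.08) there, although its member Sncg, which is also in the dopaminergic list, was at 5.15. In the dentate gyrus, Lrrk2, a kinase gene, was 2.84-fold below cortex (-1.50, -2.18 to -0.89) and Calb1, a calcium-buffering protein gene that is also a cortical marker, was 4.92-fold above it (2.30, 2.19 to 2.40).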
